A study of Mus musculus with 2 samples.

How the data were processed

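Expression was measured in endothelial cells isolated from mice of the C57Bl/6 strain that carry a Tie2-driven Cre recombinase, treated with GFP or with NeuroD1. There was 1 library per group, 2 in all. Per the labels' protocols, cells of 3 mice were collected, 10000 cells were lysed, and RNA was reverse transcribed with primers of DRUG-seq, a plate-based method that adds a barcode at the 3' end of the transcript. The labels give neither vector, dose, time after treatment nor whether these animals had a stroke.

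The authors deposited 1 table of FPKM values (fragments scaled by exon length and library total) for 53465 Ensembl mouse genes, with 1 column per library. The submitters' processing notes name Bowtie2 2.3.5.1, featureCounts 1.6.3, DESeq with no version and the GRCm38 build. How strand, reads that map to several places and molecular identifiers were treated is not given in the sources used here. A GFP sequence was not analysed here.

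Depth was recovered from the values. FPKM multiplied by merged exon length in GENCODE M21, an annotation of GRCm38, is a whole multiple of 1 step per library. The step was 452.7 in the GFP library and 512.7 in the NeuroD1 library, and 51162 genes (95.7%) gave whole reads in both within 0.02 reads. The library totals implied by the steps had a ratio of 1.13, as had median-of-ratios size factors of the recovered reads, while the recovered reads themselves summed to 2011130 and 2001426. The deposited FPKM were therefore taken as already scaled between the libraries. Reads were not recovered for 2303 genes, which have no interval below.

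Differences are log2(FPKM + 1) in NeuroD1 minus GFP, a scale that understates the change of low genes. Genes with an FPKM of at least 5 in one library or both were counted as higher or lower at a log2 difference of at least 1 on this scale, which is what 2-fold higher or lower means for counts of genes and of list members. Ratios of FPKM have exact Clopper-Pearson 95% intervals from the recovered reads. Reads were not shown to be independent molecules, so intervals cover counting error only. With 1 library per group no difference has a replicate check, and no p-value was computed.

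The 39 gene lists were fixed before the data were examined. Members with an FPKM of at least 1 in one library or both counted as measured, also in counts of 2-fold differences. Each list's median difference was placed among 10000 random lists of the same size, drawn from protein-coding genes in 20 bins of mean FPKM. A list with at least 5 measured members stood apart at a percentile of at most 2.5 or at least 97.5, also after the overall median was subtracted. The percentile describes these libraries only.

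Named genes followed a rule fixed before the data were examined. It took Neurod1, the 12 highest and 12 lowest differences among genes past the FPKM minimum with predicted genes and symbols marked -ps left out, and, of lists that stood apart or were discussed, up to 4 members with the largest differences and the 2 with the highest mean FPKM. A ranking by interval limit was added after seeing the data. It took protein-coding genes past the FPKM minimum with at least 20 reads over both libraries, with the same symbols left out. Other genes named outside the rule are said to be so. The values of 1 gene that the rule takes are not reported here.

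The steps were tested on simulated data for the NeuroD1 against GFP comparison, with 51162 genes of which 200 were changed. Reads came back exactly for 100% of genes in both libraries. Run on the protein-coding rows alone, the same step returned exact reads for only 4.03% and 4.29% of genes, so the recovery holds for the full table only. Of genes changed 2-fold, 4-fold and 8-fold, 32.8%, 93.9% and 97.0% passed the log2 threshold, and 128 of 5162 unchanged protein-coding genes passed it too. Intervals covered the true fold in 97.0%, 90.9% and 92.5% of the changed genes. Among 500 simulated lists of 20 genes, 5% stood apart with no shift, 89.2% with a 1.25-fold shift and 100% with a 1.5-fold shift. The simulated reads varied by counting error only. In the data the variance between the libraries was 1.76 times counting variance for protein-coding genes with at least 20 reads, so these rates hold for quieter data than these.

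Alternatives were other pseudocounts, other FPKM minimums, other scalings between the libraries, gene classes left out with the rest rescaled, and for lists another minimum, the mean and unmatched random lists. Added after seeing the data were protein-coding genes only, a minimum of 20 reads, subtraction of the median FPKM of chemoreceptor genes, leaving out genes above 1000 FPKM, and other pools of random lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.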

Results

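Endothelial cells line blood vessels, and NeuroD1 is a transcription factor of neuronal differentiation. The series profiled isolated endothelial cells of mice treated with GFP or NeuroD1, in a study of gene therapy after ischemic stroke, with 1 library per group. Recovered reads came to 2011130 in the GFP library and 2001426 in the NeuroD1 library. Of these, 19 genes above 1000 FPKM took 52.3% and 57.4%, and the predicted gene Gm10800 alone took 37.7% and 41.9%. That left 958799 and 851964 reads for the other genes, with a median of 24 and 20 reads per protein-coding gene.

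The comparison asks how expression differed in endothelial cells of NeuroD1-treated and GFP-treated mice. Neurod1 itself (ENSMUSG00000034701, GRCm38 chromosome 2, 79452521 to 79456751, minus strand) stood at 0.664 FPKM in the GFP library and 182 FPKM in the NeuroD1 library. These values rest on 4 and 970 reads and give a ratio of 275 (95% interval 107 to 1010). Gene totals cannot tell reads of a delivered NeuroD1 sequence from those of the mouse gene. The species of the delivered sequence is not in the labels. The endothelial markers Pecam1, an adhesion molecule, at 12.4 and 14.4 FPKM, and Cldn5, a tight junction protein, at 33.9 and 31.5 FPKM, were present in both libraries. Pecam1 is outside the naming rule and was named after its values were seen. The list of immediate early and heat shock genes was lower in NeuroD1, and neuron markers were higher. Split after the values were seen, the 9 heat shock members of the former list lay within their random lists (percentile 10.4).

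Both libraries also held reads in genes that endothelial cells are not known to use. Of 1512 chemoreceptor genes, the receptors for odours, pheromones and taste, 97.7% in the GFP library and 96.03% in the NeuroD1 library were above 0. Their median was 1.54 and 1.40 FPKM, against 3.10 and 2.98 FPKM for all protein-coding genes. The 95th percentile of chemoreceptor genes was 4.37 FPKM in GFP and 4.79 FPKM in NeuroD1. Values of list members and named genes below these lie within the chemoreceptor range, and the 1 FPKM minimum for list members lies below the chemoreceptor median. At the chemoreceptor median, a gene of the length of Neurod1 would hold 9.30 reads in the GFP library, more than the 4 found for Neurod1. All 37 mitochondrially encoded genes were listed at 0 in both libraries.

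**Figure D1:**
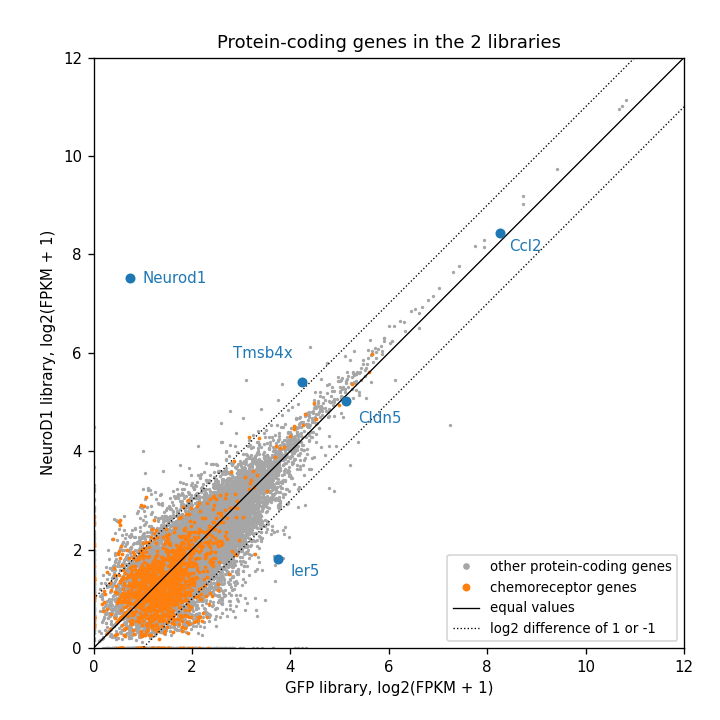
Each point is a protein-coding gene, with log2(FPKM + 1) in the GFP library on the horizontal axis and in the NeuroD1 library on the vertical axis, and genes above 12 on either axis lie outside the plot. Neurod1, at 0.664 and 182 FPKM, lies apart from the diagonal, and chemoreceptor genes (orange) overlap the bulk of other genes.

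Among 14679 genes past the FPKM minimum, 1887 were at least 2-fold higher and 2295 at least 2-fold lower in NeuroD1, so that 45.1% of the genes past a 2-fold difference were higher. With both libraries scaled to the same sum of FPKM, the share was 31.8%, and with mitochondrial, ribosomal protein and haemoglobin genes left out before the same scaling it was 32.0%. With the 19 genes above 1000 FPKM left out before that scaling, it was 45.5%, near the main value. Among genes at 5 FPKM or more in both libraries it was 59.1%. Of the higher genes 89.0% and of the lower genes 90.8% were not protein-coding, and 88.4% of those with recovered reads had under 20 reads over both libraries. Among 6408 protein-coding genes, 208 were higher and 212 lower. Counting noise alone, simulated 100 times on genes with recovered reads, gave a mean of 1320 higher and 1296 lower genes, against 1851 and 2258 observed among such genes. For protein-coding genes it gave a mean of 69.1 higher and 68.0 lower, against 185 and 189 observed. Of 14791 protein-coding genes with at least 20 reads, 12.1% had an interval that excluded 1, and of 651 chemoreceptor genes 10.4% did. The variance between the libraries was 1.76 times counting variance for the former and 1.88 times for the latter. The intervals given here are therefore narrower than the spread between these libraries.

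Across genes past the minimum, which are not independent replicates, log2(FPKM + 1) had a Pearson r of 0.241 and a Spearman rho of 0.144 between the libraries. Over protein-coding genes r was 0.753 and rho 0.468, and over the 5638 of them with recovered reads r was 0.762. Counting noise alone, simulated on genes with recovered reads, gave a mean r of 0.428 over those past the minimum and 0.862 over the protein-coding ones among them.

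The 12 highest differences were Neurod1 and 11 antigen receptor gene segments such as Trbd2 and Traj12, which are 14 to 63 bases long and had 1 to 3 reads. The 12 lowest were 11 such segments, among them Ighd5-4 and Traj33 with 1 to 5 reads, and the small RNA Vaultrc5 with 6 reads in GFP and 0 in NeuroD1. By the ranking added after seeing the data, among genes past the FPKM minimum, Nme9, Klra8 and Ncdn followed Neurod1 on the higher side. Nme9 stood at 1.36 FPKM in GFP and 8.02 FPKM in NeuroD1 (ratio 5.89, interval 2.23 to 19.6), Klra8, a natural killer cell receptor, at 1.15 and 8.27 FPKM (ratio 7.17, interval 2.11 to 37.8), and Ncdn, a neuronal protein, at 1.46 and 5.25 FPKM (ratio 3.59, interval 1.83 to 7.54). Further down, and named for its higher reads, Tmsb4x, an actin-binding peptide, had 54 and 110 reads (ratio 2.31, interval 1.65 to 3.26). The lower side began with Cmc2, which had 23 reads in GFP and 0 in NeuroD1 and an upper limit of its ratio of 0.197. It was followed by Ier5, an immediate early gene, at 12.4 and 2.504 FPKM (ratio 0.201, interval 0.110 to 0.345), Elane, a neutrophil protease, with 26 and 3 reads (ratio 0.131, interval 0.0253 to 0.426), and Gins1, a DNA replication factor, with 25 and 3 reads (ratio 0.136, interval 0.0263 to 0.445).

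The median difference of protein-coding genes depended on mean FPKM. It was -0.07 at 1 to 2 FPKM, 0.03 at 5 to 10 FPKM and 0.32 at 50 to 1000 FPKM, where 93.8% of 48 genes were above 0. At 20 to 50 FPKM it was 0.23, with 85.2% of 162 genes above 0. List medians are therefore set against random lists matched on mean FPKM. The 20 bins used hold equal numbers of genes, so the highest spans from under 10 FPKM upward. Matching thus leaves part of the trend among abundant members. Ratios and intervals of single genes were not adjusted for the trend.

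**Figure D2:**
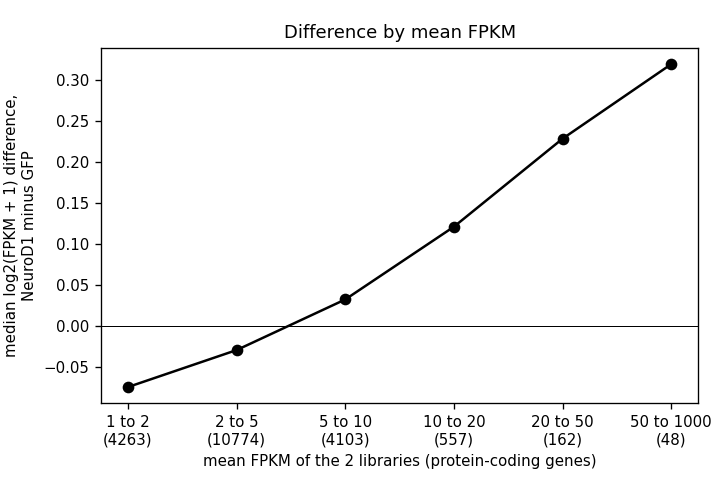
Points give the median log2(FPKM + 1) difference, NeuroD1 minus GFP, of protein-coding genes in bins of mean FPKM over both libraries, with the number of genes in parentheses. The median was -0.07 in the lowest bin and 0.32 in the highest.

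Of 38 lists with a percentile, 4 stood apart. The percentiles alone would pass 1.9 lists by chance if genes varied independently, but genes of a list may vary together. Immediate early and heat shock genes, which respond within minutes to stimulation or stress, had a median difference of -0.24 (percentile 0), with 5 of 27 measured members above 0. Egr1 stood at 13.3 FPKM in GFP and 7.43 FPKM in NeuroD1 (ratio 0.558, interval 0.408 to 0.756), Junb at 23.6 and 16.04 FPKM and Nr4a1 at 26.7 and 16.2 FPKM. Jund, at 7.06 and 12.6 FPKM, and the heat shock gene Hspa1b, at 43.6 and 57.1 FPKM (ratio 1.31, interval 1.11 to 1.55), were higher in NeuroD1. Most protein-coding genes as abundant as Hspa1b were higher as well. No member passed the log2(FPKM + 1) threshold of 1, although Egr2, at 4.40 and 1.81 FPKM, had a plain FPKM ratio of 0.412 (interval 0.194 to 0.818). Egr2 is outside the naming rule and was named after its values were seen.

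Neuron markers had a median difference of 0.39 (percentile 99.99), with 14 of 20 above 0 and none past the log2(FPKM + 1) threshold of 1. Snhg11, a neuronal noncoding RNA, stood at 2.92 and 5.72 FPKM (ratio 1.96, interval 1.39 to 2.78), and Slc17a7, a vesicular glutamate transporter, at 3.44 and 5.42 FPKM (ratio 1.57, interval 1.04 to 2.41). Rbfox3, at 26.8 and 31.02 FPKM, had an interval of 0.996 to 1.35. The list's median FPKM was 2.44 in GFP and 3.36 in NeuroD1, near the 2.98 FPKM median of all protein-coding genes in NeuroD1. Among members at 5 FPKM or more the percentile was 96, short of the threshold.

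Microglia markers had a median of -0.27 (percentile 1.79), with 3 of 18 above 0. Ctss, a lysosomal protease, stood at 5.33 and 3.78 FPKM (ratio 0.708, interval 0.287 to 1.66), whereas Tyrobp, a signalling adaptor, stood at 11.5 and 17.7 FPKM (interval 0.784 to 3.06). Ribosomal protein genes had a median of 0.19 (percentile 98.0), with 23 of 34 above 0, and Rpl32, at 2.82 and 11.7 FPKM (ratio 4.15, interval 1.63 to 12.5), was the only member whose interval excluded 1. Rpl27 stood at 10.3 and 6.35 FPKM (interval 0.332 to 1.10) and Rpl41 at 23.3 and 27.7 FPKM (interval 0.822 to 1.72). Among members at 5 FPKM or more, neither list stood apart, at percentiles of 15.2 and 82.2. Scaling both libraries to the same sum of FPKM moved the median of all measured protein-coding genes from -0.02 to -0.20 and that of the ribosomal list to -0.013, still at percentile 99.

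**Figure D3:**
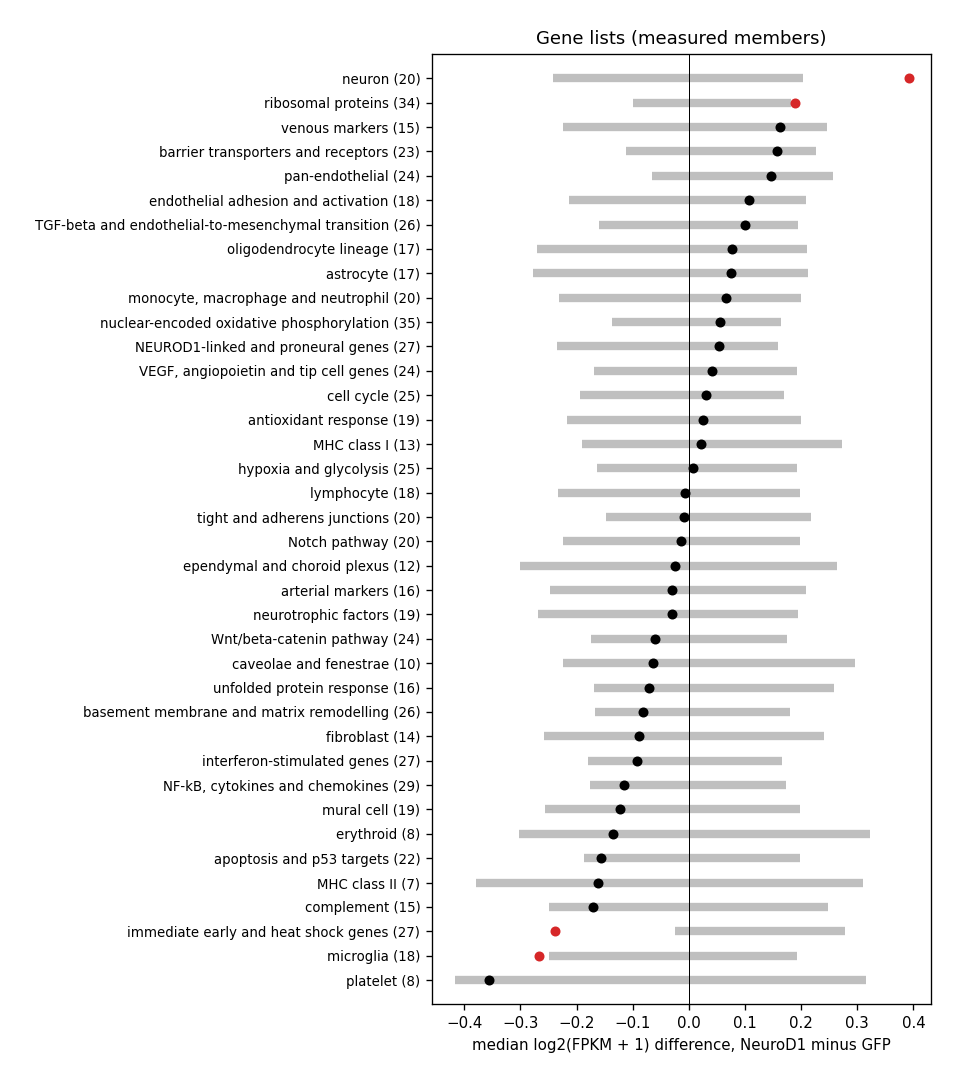
Points are the median log2(FPKM + 1) difference, NeuroD1 minus GFP, of each gene list, with the number of measured members in parentheses, and grey bars span the central 95% of 10000 matched random lists. The 4 lists in red stood apart, from microglia at -0.27 to neuron at 0.39, and the ribosomal median is below 0 with both libraries scaled to the same sum of FPKM, which moves all genes.

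The list of NEUROD1-linked and proneural genes had a median of 0.05 (percentile 79.3), and of 27 measured members Neurod1 alone passed the log2(FPKM + 1) threshold of 1. Without Neurod1, the 26 others had a median of 0.05 (percentile 81.8). Ebf1 stood at 7.70 and 7.04 FPKM and Hes6 at 5.76 and 5.96 FPKM. Of the 26, the intervals of 2 lay above 1 and that of 1 below it. Outside the naming rule and named after their values were seen, these were Sox11 (48 and 68 reads, ratio 1.605, interval 1.09 to 2.37), Sox4 (1 and 10 reads, ratio 11.3, interval 1.61 to 491.5) and Srrm4 (76 and 41 reads, ratio 0.611, interval 0.407 to 0.905). Such a share is near the 12.1% of protein-coding genes with at least 20 reads whose interval excluded 1. Sox4 stood at 0.094 and 1.07 FPKM, below the chemoreceptor median in each library.

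Pan-endothelial markers had a median of 0.15 (percentile 70.9) with 15 of 24 above 0. Chosen after their values were seen, Vwf stood at 6.06 and 8.11 FPKM (ratio 1.34, interval 1.11 to 1.61) and Egfl7 at 5.56 and 9.88 FPKM (ratio 1.78, interval 1.20 to 2.65). Barrier transporters and receptors had a median of 0.16 (percentile 88.2). The thiamine transporter Slc19a3, at 22.6 and 30.4 FPKM (ratio 1.35, interval 1.08 to 1.68), was higher in NeuroD1, as were most genes of similar FPKM. The monocarboxylate transporter Slc16a1 was lower, at 8.49 and 4.75 FPKM (ratio 0.560, interval 0.375 to 0.823). The glucose transporter Slc2a1 stood at 33.4 and 36.0 FPKM (interval 0.900 to 1.29). Tight and adherens junction genes had a median of -0.01 (percentile 28.8), with Cldn12 at 34.8 and 44.9 FPKM and Marveld2 at 6.16 and 2.43 FPKM. Matrix genes had a median of -0.08 (percentile 15.1), with the protease Mmp9 at 5.24 and 2.32 FPKM (ratio 0.442, interval 0.232 to 0.805) and Adamts1 at 10.4 and 5.80 FPKM.

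NF-kB, cytokine and chemokine genes had a median of -0.11 (percentile 9.69), with 3 of 29 measured members at or above 1 and 4 at or below -1 on the log2(FPKM + 1) scale. Il1b stood at 2.14 and 7.26 FPKM (ratio 3.40, interval 1.55 to 8.21) and Il6 at 5.97 and 2.96 FPKM (ratio 0.496, interval 0.244 to 0.955). Interferon-stimulated genes had a median of -0.09 (percentile 14.8), with the RNA sensor Ddx58 at 5.46 and 2.55 FPKM (ratio 0.466, interval 0.305 to 0.699). The list of endothelial adhesion and activation had a median of 0.11 (percentile 83.3). Its largest differences were those of Lrg1, a secreted glycoprotein, at 1.005 and 8.35 FPKM with no recovered reads and so no interval, and Csf3, a granulocyte growth factor, at 9.61 and 3.63 FPKM (ratio 0.378, interval 0.165 to 0.794). The adhesion molecule Icam1 stood at 7.79 and 4.70 FPKM (ratio 0.604, interval 0.401 to 0.898). Complement genes had a median of -0.17 (percentile 8.48), with C3 at 7.04 and 3.89 FPKM.

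Among markers of other cell types, the medians were 0.07 for astrocytes (percentile 75.1), 0.08 for the oligodendrocyte lineage (percentile 76.9), -0.12 for mural cells (percentile 20.9) and -0.36 for platelets (percentile 4.96). Median FPKM of astrocyte markers was 2.91 in GFP and 2.70 in NeuroD1, against 9.01 and 10.7 FPKM for pan-endothelial markers.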

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

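Settings with protein-coding genes only, at least 20 reads, chemoreceptor background subtracted, genes above 1000 FPKM left out and other pools of random lists were chosen after seeing the data. No paired analysis was possible because each group has 1 library, which also leaves no replicate to leave out. The counts of genes at least 2-fold higher and lower, 1887 and 2295, were 1061 and 1387 with a pseudocount of 5, 4343 and 6195 with no filter, 214 and 211 at an FPKM of at least 20, 237 and 164 at 5 in both libraries, 208 and 212 for protein-coding genes and 98 and 103 for those with at least 20 reads. Fewer or more genes tested change these counts under the filter settings by construction. The number of genes does not account for the share that was higher, 59.1% at 5 FPKM in both libraries against 45.1% at first. The higher count was 1252 with mitochondrial, ribosomal protein and haemoglobin genes left out and the rest scaled to the same sum of FPKM, a setting that changes both choices at once and scales almost as the same sum of all genes does. The correlation across genes, 0.241, was 0.0297 with a pseudocount of 0.1, 0.522 with 5, 0.524 with no filter, 0.479 at an FPKM of 20, 0.866 at 5 in both, 0.155 without genes above 1000 FPKM, 0.753 for protein-coding genes and 0.843 with at least 20 reads. The Neurod1 difference, 6.78, was 5.05 with a pseudocount of 5. Immediate early and heat shock genes stood apart in the same direction under all settings run, with medians from -0.47 to -0.20, and neuron markers under all but 1, the minimum of 5 FPKM (median 0.42, percentile 96). Microglia fell short of the threshold with a pseudocount of 0.1 (-0.35), at 5 FPKM (-0.27), with the mean (-0.25), and with random lists from all genes (-0.27) or matched on reads (-0.27). Ribosomal proteins fell short with a pseudocount of 5 (0.10), background subtracted (0.26), at 5 FPKM (0.16), with the mean (0.17) and with random lists from all genes (0.19), and had a median of -0.013 with both libraries scaled to the same sum of FPKM, which moves all genes alike and left the list at percentile 99. With the same sum of FPKM over all genes, and with those classes left out before that scaling, the medians were -0.064 and -0.064 for pan-endothelial, -0.050 and -0.050 for barrier, and -0.12 and -0.14 for proneural genes. The barrier median was 0.065 as a mean, and the proneural one 0.18 with background subtracted and 0.27 (percentile 99.95) as a mean, which holds Neurod1. Lists within their random lists at first passed a threshold at 5 FPKM (venous 0.53, complement -0.45, oxidative phosphorylation 0.39), as a mean (oxidative phosphorylation 0.24), with a pseudocount of 5 or the gene classes left out and the rest scaled (apoptosis and p53 targets -0.11 and -0.36), with background subtracted (NF-kB -0.21, erythroid -0.59) and with random lists matched on reads (matrix -0.13). For the rest, the cause was not tested. Of named gene differences under other settings, 1772 moved by less than counting error and 7 by more, while 484 had no bounded interval to compare with. Settings that change only which genes are counted leave a gene's own difference unchanged, so part of the 1772 could not move. Intervals are also wide at low reads, so this tally is no measure of how stable the differences are. Depth limits most genes, with a median of 20 to 24 reads per protein-coding gene.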

Other observations

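The tests of genomic DNA and of the endothelial share were chosen only after the result was seen. The tests on shared sequence and on second lists were written before their values were computed, but after the patterns were seen.

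Cell state lists other than ribosomal proteins, and signalling lists, lay within their random lists under the main setting. Medians were 0.03 for cell cycle (percentile 62.9), 0.01 for hypoxia and glycolysis (percentile 41.3), 0.06 for nuclear-encoded oxidative phosphorylation (percentile 65.7), -0.07 for the unfolded protein response (percentile 12.1) and -0.16 for apoptosis and p53 targets (percentile 4.66). Under other settings oxidative phosphorylation reached percentile 99.85 and apoptosis and p53 targets 1.65. The VEGF and tip cell list had a median of 0.04 (percentile 58.8), Notch genes -0.01 (percentile 47.0), Wnt genes -0.06 (percentile 22.8) and TGF-beta and mesenchymal transition genes 0.10 (percentile 80.1). Venous markers had a median of 0.16 (percentile 91.2, and 99.6 among members at 5 FPKM or more) and arterial markers -0.03 (percentile 45.9).

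Chemoreceptor genes held reads in both libraries. Reads shared between near-identical copies are argued against, since 252 of these genes with under 1% of their 31-base words in transcripts of other genes had a median FPKM at least 0.984 times that of all chemoreceptor genes in both libraries, although copies outside annotated transcripts were not searched. Genomic DNA counted as transcripts stays open, since X-linked lincRNAs and processed pseudogenes had medians at most 0.573 times the autosomal ones in both libraries, as DNA of male animals would give. Low transcription from a single X could give the same ratio, and the sex of the animals is not in the labels. Neurod1 reads may then include vector DNA, which gene totals cannot separate from RNA, and no biological explanation was tested.

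Neuron markers were higher in NeuroD1. A lower share of endothelial cells would put the pan-endothelial median below its random lists and glial and mural cell markers higher. This expectation was written after the values were seen. The pan-endothelial median was instead 0.15, at percentile 70.9. Astrocyte (0.07) and oligodendrocyte lineage (0.08) medians were above 0 but within their random lists (percentiles 75.1 and 76.9). Microglia (-0.27) and mural cell (-0.12) medians were below 0, the latter within its random lists (percentile 20.9). The bound set to exclude a lower share was microglia standing apart under every setting, and it was not met. That bound was made stricter after the values were seen, so this test cannot decide and a lower share stays open. More neurons or neuronal RNA also stays open, since a second list of 30 neuronal genes with no gene in common had a median of 0.04 at percentile 69.6, so the difference did not extend to it past the threshold, nor was it at the percentile of 50 or below set to exclude it. Rbfox3 and Nrgn, the most abundant markers, stood at 26.8 and 31.02 FPKM and at 9.97 and 13.8 FPKM. An effect of NeuroD1 on endothelial cells was not tested apart from this, with 1 library per group.

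Immediate early and heat shock genes were lower in NeuroD1. A stress response that differed with handling or treatment may account for this, but a second list of 28 immediate early genes, 27 of them measured, had a median of -0.04 at percentile 18.4 and did not stand apart. Split after the values were seen, the 18 immediate early members of the first list had a median of -0.26 (percentile 0.03) and its 9 heat shock members -0.06 (percentile 10.4). Handling and treatment cannot be told apart here, because each group has 1 library.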
